A study of Mus musculus with 12 samples.

How the data were processed

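Lungs of newborn C57/Bl6 mice were taken after the lavage fluid had been removed, per the labels' protocols. Total RNA was amplified to cDNA with the NuGEN Ovation RNA-Seq System V2, made into libraries with Nextera XT and sequenced as paired-end 75 bp reads on a HiSeq 2500, per the labels' protocols. The authors deposited a table of raw counts per gene symbol for 12 libraries, not normalized and with no replicates pooled. Bowtie2, Cufflinks, DESeq and the genome build mm10 are named without versions, per the submitters' processing notes. The counting tool, its treatment of strand and of reads that match several places, and the gene annotation are not given in the sources used here. Reads from near-identical copies may therefore have been split or dropped, and such genes are called uncertain. Amplified reads are not independent molecules, so floors cover counting error only. A floor of 3 counts per library was used as the limit for a count of 0.

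Each column was matched to its sample by its name, and groups came from the labels (2 injections by 2 oxygen conditions, 3 samples each). Total counts ranged from 14331749 to 20486735 per library. Of 23478 genes, 3350 had no count in any library. Symbols were looked up in a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, where 21912 matched by symbol and 1442 by synonym, and positions come from that table. The genes printed with a position are annotated there as protein-coding, and the position spans the gene with its exons and introns. Replicates were compared first. Over the genes, chi-square per degree of freedom between replicates ran from 6.83 to 41.9, so no pair agreed within sampling noise, and Pearson's r of log2 CPM ran from 0.965 to 0.981. The 20 most abundant genes held 8.71% to 10.0% of each library.

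Genes were kept by filterByExpr with the group (minimum count 10, minimum total 15), which left 15761 genes with 99.96% of the counts. Counts were scaled by TMM and fitted over all 12 samples with 1 mean per group by edgeR's quasi-likelihood test (edgeR QL: glmQLFit and glmQLFTest), with 8 residual degrees of freedom. P-values are two-sided and were adjusted by Benjamini-Hochberg, with a threshold of 0.05. The common biological coefficient of variation was 18.7% and the median over genes 15.0%. The 7 contrasts were aurothioglucose against saline in room air, in hyperoxia and averaged, hyperoxia against room air in saline, in aurothioglucose and averaged, and their interaction. Levels are CPM with TMM scaling, and the components used log2 CPM with a prior count of 2. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

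Gene lists were tested by limma's camera on the fit, with a preset inter-gene correlation of 0.01, adjusted over the 30 lists within a contrast. Camera with an estimated correlation and fry were run beside it. Fry tests whether a list's genes move on balance 1 way, and does not compare the list with other genes. For the drug the NRF2 list passed fry in room air (adjusted p = 0.0435), in hyperoxia (0.00561) and in the average (0.00146). The 30 lists hold NRF2 targets, metallothionein and heat shock genes, selenoprotein genes, p53 targets, cell cycle genes, angiogenic ligands, receptors and transcription factors, lung endothelial markers, HIF targets, integrated stress response genes, cytokine and acute phase genes, and interferon response genes. They also hold markers of alveolar type 2, type 1, ciliated, and club and secretory cells, matrix and myofibroblast genes, markers of macrophages, neutrophils, B, T and NK cells, erythroid cells, thymocytes, cardiomyocytes, skeletal muscle, adipocytes, mesothelium, and squamous epithelium and cartilage. The last lists are clock genes, immediate early genes, glucocorticoid-responsive genes and sex-linked genes. Ighm, Ahsp and Muc16 were not found in the table. A gene can be in several lists, as Slc7a11, Txnrd1 and Cdkn1a are.

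The groups, contrasts, tests, lists, named-gene rule and most alternatives were set before the data were examined. The rule takes, per contrast, genes past the threshold with a mean of at least 5 CPM and no overlap between the samples of the groups, leaving out predicted gene models and sex-linked genes. Averaged contrasts demand this in both strata, and the interaction does not demand it. From these come the 10 largest rises and the 10 largest falls. To them are added up to 4 members per list with the smallest adjusted p under 0.05, and fixed genes whatever their p. Those are Txnrd1, Nqo1, Gclm, Hmox1, Srxn1, Slc7a11, Mt1, Mt2, Vegfa, Kdr, Flt1, Pecam1, Angpt1 and Epas1 for the drug, and Cdkn1a, Nqo1, Vegfa, Kdr, Mki67 and Sftpc for hyperoxia. Where no gene passes, the 5 with the smallest p are named as not passing.

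Alternatives were DESeq2, limma-voom, RLE size factors in place of TMM, no filter on low counts, the replicate number as a block, a fit of the 6 samples compared, a minimum of 5 CPM for the correlations, an estimated inter-gene correlation, sex as a covariate and each library left out in turn. Chosen after seeing the data were leaving out both libraries rich in Nppa, leaving out those and the library rich in Myh8, the mean of the cardiac markers as a covariate, sex as a covariate for the lists, and exact permutation of list means within strata. Sex was read from Xist and Y-linked counts. Other splits of the samples were fitted anew, all 10 for groups of 3 and 100 drawn ones for larger contrasts (seed 1).

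The steps were tested on simulated data made from the real means and library sizes. In each run 67, 67 and 66 genes among 15761 were changed 1.5-, 2- and 4-fold. For aurothioglucose in room air, 16.4%, 62.7% and 90.9% of genes changed 1.5-, 2- and 4-fold were recovered. For hyperoxia in saline the shares were 31.3%, 68.7% and 87.9%, for the interaction 5.97%, 50.7% and 65.2%, for the averaged drug 52.2%, 85.1% and 95.5%, and for averaged hyperoxia 59.7%, 73.1% and 93.9%. False calls were 7.38% of all calls in the first, 3.85% in the second, and 6.90%, 6.06% and 6.21% in the others, mostly above the 5% that the threshold aims at. An NRF2 list shifted by 0.2 in the averaged drug contrast was recovered at 0.22, with 0 of 27 other lists called. The simulated genes were drawn independently, so that run does not test camera's preset correlation on genes that move together. A change near 1.5-fold in 3 against 3 samples can therefore be missed at this depth and spread.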

Results

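Gene expression was measured by RNA-seq in whole lungs of newborn C57/Bl6 mice after removal of the lavage fluid. On day 0 the pups received an intraperitoneal injection of 25 mg/kg aurothioglucose (ATG), a gold compound that inhibits thioredoxin reductase, or of saline. They were then kept for 72 h in more than 95% oxygen (hyperoxia) or in room air. The 12 samples formed 4 groups of 3. The total count per sample was 14331749 to 15916703 in saline room air, 14589812 to 17368904 in ATG room air, 16490223 to 19267023 in saline hyperoxia and 18009965 to 20486735 in ATG hyperoxia. Of 23478 genes in the table, 15761 had enough counts to be tested. The labels do not tell animals or litters apart, so p-values measure only sample spread. It may be technical, but only in part where a group held both sexes (not saline room air).

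The libraries differed in genes of tissues that lie beside the lung. Nppa, the atrial natriuretic peptide gene, stood at 270 CPM (the count scaled to a common library size) in saline hyperoxia 2 and at 1108 CPM in ATG hyperoxia 2, against 1.85 to 3.55 CPM in the other libraries. Myh6, the cardiac myosin heavy chain, stood at 919 and 1645 CPM in those libraries and at 89.3 to 244 CPM in the others. Myh8, a skeletal muscle myosin of the newborn, reached 175 CPM in saline hyperoxia 1 and 15.3 CPM in ATG room air 2. Rag1, which recombines antigen receptor genes in thymocytes, reached 39.2 CPM in saline hyperoxia 2 and 15.0 CPM in saline hyperoxia 3. Xist and the Y-linked genes assigned 3 males to saline room air, 2 females and 1 male to aurothioglucose room air, 2 females and 1 male to saline hyperoxia, and 1 female and 2 males to aurothioglucose hyperoxia. The first principal component of the 500 most variable genes held 27.2% of their variance and was led by ATG hyperoxia 2 (score 34.5) and saline hyperoxia 2 (score 26.8). On the second, with 19.0%, the other hyperoxia libraries scored 16.1 to 18.1.

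**Figure D1:**
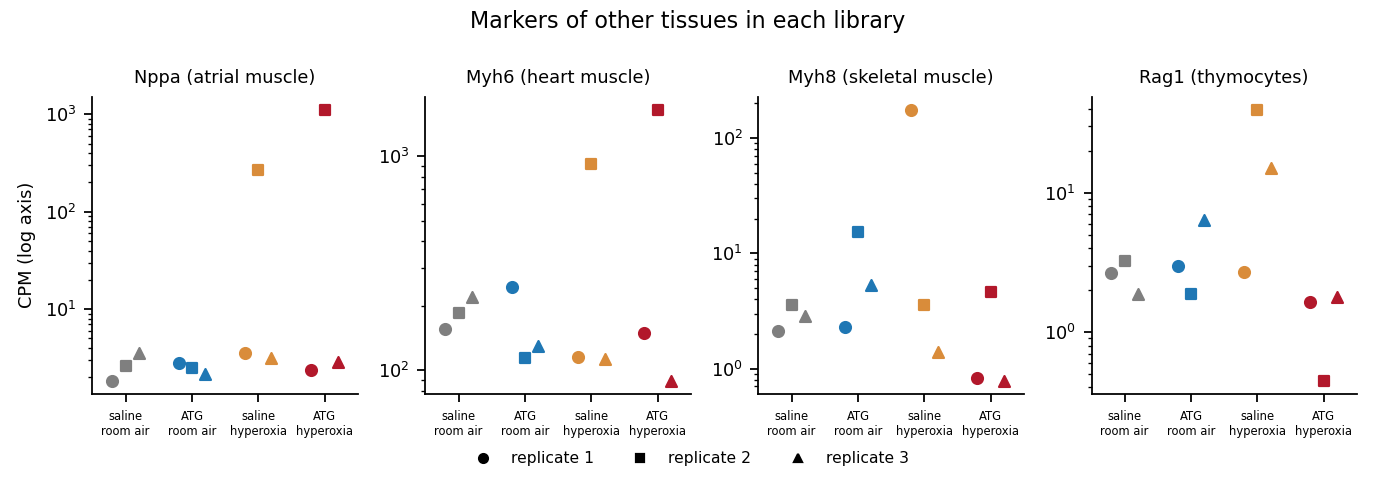
Levels of Nppa and Myh6 (heart), Myh8 (skeletal muscle) and Rag1 (thymocytes) in each of the 12 libraries, in CPM on a log axis, each point 1 library. Nppa stands at 270 CPM in saline hyperoxia 2 and 1108 CPM in ATG hyperoxia 2, Myh8 at 175 CPM in saline hyperoxia 1 and Rag1 at 39.2 CPM in saline hyperoxia 2.

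Hyperoxia was compared with room air to ask which lung genes high oxygen changed, once in saline-injected and once in drug-injected pups. Target genes of p53, the transcription factor activated by DNA damage, rose after both injections, and genes of the cell cycle fell. Cdkn1a (chromosome 17, 29090979 to 29100722), which encodes the p21 inhibitor of cyclin-dependent kinases, rose from 128 ± 2.44 to 976 ± 298 CPM in saline and from 145 ± 19.2 to 1015 ± 406 CPM in ATG (mean ± SD, n = 3). Its log2 fold changes were 2.93 (SE 0.27) and 2.80 (SE 0.27), with edgeR QL adjusted p = 2.4e-05 and 2.5e-05. Eda2r (chromosome X, 97333837 to 97377234), a receptor of the TNF family, rose by 4.48 (SE 0.34) and 4.44 (SE 0.34) from 3.42 and 3.14 CPM. Ccng1, the cyclin G1 gene, rose by 2.19 and 2.28. Of 20 p53 targets, 16 rose in saline and 4 did not pass, while 15 rose in ATG and 5 did not pass. Adjusted over the list alone, 17 were higher and 1 lower in saline, and 18 were higher and 1 lower in ATG. The list's median log2 fold change was 1.44 in saline (camera adjusted p = 2.75e-43, and adjusted p = 0.00889 with an estimated correlation) and 1.45 in ATG (1.05e-34, and adjusted p = 0.0149 with an estimated correlation).

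Mki67 (chromosome 7, 135689784 to 135716450), the gene of the proliferation antigen Ki-67, went from 953 ± 252 to 309 ± 112 CPM in saline and from 1011 ± 348 to 229 ± 65.5 CPM in ATG. It fell by 1.63 (SE 0.30, edgeR QL adjusted p = 0.00446) and by 2.14 (SE 0.31, adjusted p = 0.000549) on the log2 scale. Plk1, a mitotic kinase, fell by 1.87 and 2.18, Aurkb, the aurora B kinase, by 1.43 and 2.04, and Mcm6, part of the replicative helicase, by 0.90 and 0.90. Of 25 cell cycle genes, 23 fell in saline and 2 did not pass, and 25 of 25 fell in ATG. In each, 25 were lower adjusted over the list alone. The medians were −1.45 and −1.77 (camera adjusted p = 1.52e-31 and 1.58e-41). With an estimated correlation the list did not pass in either (adjusted p = 0.102 and adjusted p = 0.0531 with an estimated correlation). Saline hyperoxia 2 and ATG hyperoxia 2, the Nppa-rich libraries, were each 1 of the 3 samples of their hyperoxia group.

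Antioxidant genes regulated by NRF2, the transcription factor that answers oxidants and electrophiles, rose as a group in hyperoxia. Srxn1 (chromosome 2, 152105524 to 152111376), the sulfiredoxin that reactivates peroxiredoxins, rose from 11.5 ± 1.26 to 34.9 ± 3.86 CPM in saline and from 15.2 ± 0.843 to 51.3 ± 1.13 CPM in ATG (n = 3). Its log2 fold changes were 1.60 (SE 0.12) and 1.76 (SE 0.12), with edgeR QL adjusted p = 4.36e-06 and 1.37e-06. Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose by 1.24 and 1.41. Txnrd1 (chromosome 10, 82833951 to 82897724), the cytosolic thioredoxin reductase that aurothioglucose inhibits, rose by 0.77 (SE 0.09, adjusted p = 0.00017) and 0.82 (SE 0.09, adjusted p = 7.56e-05). Gpx2 rose by 2.19 and 2.45, an uncertain value because Gpx2-ps1, a near-identical copy, can share its reads. Of 26 NRF2 targets, 20 rose in saline with 6 not passing, and 19 rose in ATG with 7 not passing. Adjusted over the list alone, 22 were higher and 1 lower in saline, and 20 were higher in ATG. The medians were 0.75 and 0.87 (camera adjusted p = 1.5e-38 and 1.11e-39), and both held with an estimated correlation (adjusted p = 0.000471 and adjusted p = 0.000209 with an estimated correlation).

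Of 13 metallothionein and heat shock genes, 4 rose in saline and 3 in ATG. Among them were Mt1 (1.20 and 1.17) and Mt2 (1.07 and 0.99), which bind metals and have uncertain reads as the copies are alike. By p adjusted over the list alone, 5 and 3 were higher. The medians were 0.35 (camera adjusted p = 0.000163, and adjusted p = 0.107 with an estimated correlation) and 0.22 (0.00855, and adjusted p = 0.282 with an estimated correlation). Without ATG hyperoxia 2, which carried the cardiac transcripts, the drug-injected median was 0.13 and its call ended. Of 18 selenoprotein genes, 3 rose in each, Txnrd1 and Gpx2 among them, and 4 were higher in each adjusted over the list alone. Their medians were 0.10 (camera adjusted p = 0.00589, and adjusted p = 0.125 with an estimated correlation) and 0.06 (0.00855, and adjusted p = 0.17 with an estimated correlation). The saline median was 0.18, 0.16 and 0.01 without saline hyperoxia 1, 2 and 3 in turn, and the drug-injected median 0.04 without ATG hyperoxia 3.

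Genes of the integrated stress response, which ATF4 drives when amino acids run short or proteins misfold, rose in hyperoxia. Asns (chromosome 6, 7675165 to 7693209), the asparagine synthetase, rose from 12.1 ± 1.59 to 33.0 ± 3.42 CPM in saline and from 11.4 ± 1.16 to 42.1 ± 6.83 CPM in ATG (n = 3). Its log2 fold changes were 1.45 (SE 0.15) and 1.89 (SE 0.15), with edgeR QL adjusted p = 6.76e-05 and 5.2e-06. Atf5, a transcription factor of this response, rose by 1.46 and 1.83. Of 15 such genes, 9 rose in saline with 6 not passing, and 12 rose in ATG with 3 not passing. In saline 13 were higher adjusted over the list alone, and 13 were higher and 1 lower in ATG. The medians were 0.74 (camera adjusted p = 2.25e-18, and adjusted p = 0.00889 with an estimated correlation) and 1.11 (7.67e-19, and adjusted p = 0.0102 with an estimated correlation).

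Clock genes lay higher in hyperoxia. Cry1, a repressor of the circadian loop, rose by 0.49 and 0.48, its call in saline ending without the 3 libraries rich in heart and muscle transcripts (0.49), here the muscle-rich libraries. Per2 rose by 0.85 (SE 0.10, edgeR QL adjusted p = 0.000138) in ATG, from 46.8 to 84.3 CPM, and its levels in saline were 52.2 and 62.5 CPM. The difference between these Per2 effects, 0.59, did not pass the interaction test (adjusted p = 1.00). Of 16 clock genes, 2 rose in saline and 6 in ATG, and 2 and 7 were higher adjusted over the list alone. The medians were 0.26 (camera adjusted p = 0.00206, and adjusted p = 0.045 with an estimated correlation) and 0.47 (1.71e-05, and adjusted p = 0.0102 with an estimated correlation).

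Of 13 immediate early genes, 4 rose in saline and 3 in ATG, Ier3 by 0.59 and 0.68, with 6 and 3 higher adjusted over the list alone. The medians were 0.68 (camera adjusted p = 6.13e-05, and adjusted p = 0.296 with an estimated correlation) and 0.42 (0.00855, and adjusted p = 0.561 with an estimated correlation). In aurothioglucose this median was 0.34 without room air 1, which ended the call, 0.66 without room air 2, 0.25 without hyperoxia 1 and 0.24 with sex as a covariate. Of 10 glucocorticoid-responsive genes, 1 rose in each, Cdkn1a, which is also a p53 target, and 1 fell in saline. Adjusted over the list alone, 1 was higher and 1 lower in saline and 3 were higher in ATG. The saline median was −0.02 while the mean, 0.28, and the camera direction were positive (adjusted p = 0.189). The drug-injected median was 0.19 (camera adjusted p = 0.0152, and adjusted p = 0.282 with an estimated correlation). It was 0.11 without room air 1, which ended the call, 0.32 without room air 3 and 0.36 without hyperoxia 3.

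Among genes of blood vessels, changes in hyperoxia went both ways. Aplnr (chromosome 2, 85136360 to 85139923), the apelin receptor of endothelial cells, went from 268 ± 17.2 to 139 ± 18.7 CPM in saline and from 278 ± 23.6 to 136 ± 9.65 CPM in ATG (n = 3). It fell by 0.95 (SE 0.10, edgeR QL adjusted p = 8.65e-05) and by 1.03 (SE 0.10, adjusted p = 3.39e-05) on the log2 scale. Calcrl, a receptor of adrenomedullin, fell by 0.58 and 0.78. Esm1 (chromosome 13, 113209659 to 113218104), a proteoglycan of endothelial tip cells, rose by 1.61 (SE 0.41, adjusted p = 0.0245) and 1.44 (SE 0.40, adjusted p = 0.03). Its saline call ended without saline room air 1 (1.36) or 3 (1.66) and without saline hyperoxia 1 (1.37) or 3 (1.56), and both calls ended with limma-voom (1.61 and 1.25). Its drug-injected call ended without ATG room air 1 (1.32) or 2 (1.40) without the Nppa-rich ATG hyperoxia 2 (0.79), without both Nppa-rich libraries (0.79) and without the 3 muscle-rich libraries (0.80). It also ended with sex (1.24) or the cardiac markers (1.14) as a covariate. Vegfa, the main vascular growth factor, stood at 365 ± 23.2 and 415 ± 65.1 CPM in saline and at 352 ± 51.8 and 407 ± 14.5 CPM in ATG, and did not pass (0.18, adjusted p = 0.386, and 0.21, adjusted p = 0.291). Its receptor Kdr did not pass either (0.10, adjusted p = 0.696, and 0.04, adjusted p = 0.894).

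Of 34 angiogenic ligands, receptors and transcription factors, 1 rose and 3 fell in saline with 30 not passing, and 1 rose and 4 fell in ATG with 29 not passing. Adjusted over the list alone, 2 were higher and 3 lower in saline, and 1 was higher and 5 lower in ATG. The saline median and mean were 0.00 and 0.00, above 0, while the camera direction was down (adjusted p = 0.616). The drug-injected median was −0.02 (camera adjusted p = 0.338). Of 20 lung endothelial markers, 1 rose and 3 fell in saline and 1 rose and 2 fell in ATG, with the same counts adjusted over the list alone. Their medians were −0.09 (camera adjusted p = 0.306) and −0.17 (0.178). Of 16 HIF targets, genes of the response to low oxygen, 4 rose and 1 fell in saline and 3 rose and 1 fell in ATG. Slc2a1, a glucose transporter, rose by 0.66 and 0.69 and the glycolytic Aldoa by 0.80 and 0.72. Adjusted over the list alone, 4 were higher and 1 lower in saline, and 6 were higher and 1 lower in ATG. The HIF medians were 0.20 (camera adjusted p = 0.0034, and adjusted p = 0.105 with an estimated correlation) and 0.25 (0.0123, and adjusted p = 0.17 with an estimated correlation). The saline median was 0.12 without saline room air 3. The drug-injected median was 0.15 without ATG hyperoxia 2 and 0.20 without room air 1, which ended the call.

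Epithelial markers also went both ways. Lmo7, a junction protein of alveolar type 1 cells, rose by 0.63 and 0.56. Of 11 type 1 markers, 5 rose in saline and 2 in ATG, and 7 and 4 were higher adjusted over the list alone. The medians were 0.34 (camera adjusted p = 0.000955, and adjusted p = 0.286 with an estimated correlation) and 0.20 (0.0883). Sftpa1, a surfactant protein of type 2 cells, fell by 0.55 and 0.59, and its saline call ended without the 3 muscle-rich libraries (−0.47). Sftpc, the surfactant protein C gene, stood at 5689 ± 202 and 6741 ± 335 CPM in saline, where it passed (0.24, adjusted p = 0.0473). That call ended without any 1 of saline room air 1 (0.27), 2 (0.22) and 3 (0.26) and saline hyperoxia 1 (0.21) and 3 (0.25), without the 3 muscle-rich libraries (0.25), with no filter on low counts (0.25), with sex (0.22) or the cardiac markers (0.25) as a covariate, and fitted on the 6 saline samples alone (0.24). In aurothioglucose Sftpc did not pass (−0.04, adjusted p = 0.788). Of 12 type 2 markers, 4 rose and 1 fell in saline and 4 fell in ATG, with the same counts adjusted over the list alone. The saline median was −0.01 while the mean, 0.01, and the camera direction were positive (adjusted p = 0.715), and the drug-injected median was −0.12 (0.0694).

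All 12 ciliated cell markers did not pass in either, also adjusted over the list alone. Their saline median was −0.24 (camera adjusted p = 0.211). Their drug-injected median was 0.05 against a mean of −0.02 (0.86). Of 8 club and secretory cell markers, 1 rose in ATG and the others did not pass in either, and adjusted over the list alone 1 was higher and 1 lower in ATG. The medians were −0.28 (camera adjusted p = 0.477) and 0.32 (0.338). Pdgfra, a receptor of lung fibroblasts and myofibroblast progenitors, fell by 0.73 and 0.80. Of 18 matrix and myofibroblast genes, 2 fell in saline and 3 in ATG, with the same counts adjusted over the list alone. The medians were −0.14 (camera adjusted p = 0.108) and −0.21 (0.0171, and adjusted p = 0.561 with an estimated correlation). The drug-injected call ended without room air 1 (−0.17) or 3 (−0.15) or the Nppa-rich hyperoxia 2 (−0.16). All 7 mesothelial markers did not pass in either, also adjusted over the list alone (medians 0.28 and 0.14, camera adjusted p = 0.211 and 0.543).

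Among immune genes, Icam1, the leukocyte adhesion molecule, rose by 0.82 and 0.81. Of 16 cytokine and acute phase genes, 1 rose and 1 fell in saline and 3 rose in ATG, and adjusted over the list alone 2 were higher and 1 lower in saline and 4 higher in ATG. The medians were 0.78 (camera adjusted p = 0.0257, and adjusted p = 0.511 with an estimated correlation) and 0.52 (0.00155, and adjusted p = 0.282 with an estimated correlation). The saline call ended without saline room air 3 (0.33), saline hyperoxia 1 (0.72) or saline hyperoxia 3 (0.38). Ifit3, an interferon-induced gene, rose by 1.07 and 1.55, and Rtp4, another, fell by 0.95 and 0.71, its drug-injected call ending without ATG room air 2 (−0.54) or ATG hyperoxia 1 (−0.70) or 3 (−0.69). Of 16 interferon response genes, 1 rose and 4 fell in saline and 1 rose and 1 fell in ATG, and adjusted over the list alone 2 were higher and 7 lower in saline and 1 higher and 1 lower in ATG. The medians were −0.45 (camera adjusted p = 0.00863, and adjusted p = 0.32 with an estimated correlation) and −0.18 (0.712). The saline call ended without saline room air 1 (−0.32) or saline hyperoxia 1 (−0.30), and the median was −0.27 with sex as a covariate.

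Of 13 macrophage markers, 1 fell in saline and 2 in ATG, with the same counts adjusted over the list alone (medians 0.16 and 0.22, camera adjusted p = 0.525 and 0.86). Siglec5, a sialic acid receptor of alveolar macrophages and eosinophils, fell by 1.97 in ATG and by 1.64 in saline, the latter call ending without saline room air 3 (−1.33) or the 3 muscle-rich libraries (−1.49). All 11 neutrophil markers did not pass in either, also adjusted over the list alone. Their medians were 0.39 (camera adjusted p = 0.66) and 0.58 (0.0496, and adjusted p = 0.767 with an estimated correlation). The drug-injected call ended without room air 1 (0.47) or 3 (0.39) or hyperoxia 1 (0.59) or 2 (0.48), with RLE size factors (0.59) and with sex as a covariate (0.47), and the median was 0.92 without room air 2. All 11 markers of B, T and NK cells did not pass in either, also adjusted over the list alone (medians 0.21 and −0.27, camera adjusted p = 0.481 and 0.229). The same held for 7 erythroid genes, whose globin copies share reads (medians −0.60 and −0.40, camera adjusted p = 0.362 and 0.189).

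Genes of other tissues moved with a few libraries. Of 6 thymocyte genes, 1, Rag1, passed in saline (2.86), and adjusted over the list alone 3 did. Their median was 2.01 (camera adjusted p = 0.0291, and adjusted p = 0.605 with an estimated correlation). The list call ended without saline hyperoxia 2 (0.93), without both Nppa-rich libraries (0.93), without saline room air 1 (2.34) and with sex as a covariate (1.48). The Rag1 call ended without saline hyperoxia 2 (1.77), without both Nppa-rich libraries (1.77), without saline room air 1 (2.89), 2 (3.06) or 3 (2.68), with sex as a covariate (2.32) and with limma-voom (2.10). Of 8 skeletal muscle genes, 1, Myh3, passed in saline (5.73), and adjusted over the list alone 4 did. Their median was 3.08 (camera adjusted p = 0.0418, and adjusted p = 0.66 with an estimated correlation). It was 0.17 without saline hyperoxia 1, 2.32 without saline room air 1 and 3.14 with sex as a covariate, which each ended the call. The Myh3 call ended without saline hyperoxia 1 (0.26), without the 3 muscle-rich libraries (−0.67), without saline room air 1 (5.42), 2 (5.76) or 3 (6.12), with sex as a covariate (4.30) and with limma-voom (2.79). In aurothioglucose all members of both lists did not pass, also adjusted over the list alone (medians −1.07 and −0.10, camera adjusted p = 0.365 and 0.829). All 10 cardiomyocyte genes did not pass in either, also adjusted over the list alone (medians 0.63 and 1.67, camera adjusted p = 0.582 and 0.0694). Of 5 adipocyte genes, 1, Cidea, passed in ATG, also adjusted over the list alone. Its 3 aurothioglucose room air libraries held 0 counts against a mean of 0.939 CPM in hyperoxia, at least 4.87-fold higher by a floor of 3 counts per library (edgeR QL adjusted p = 0.0401). The hyperoxia libraries held 0.221, 1.91 and 0.690 CPM, the highest being the Nppa-rich ATG hyperoxia 2. The Cidea call ended without ATG hyperoxia 2 (edgeR QL adjusted p = 0.119) or 3 (0.0566) and without ATG room air 1 (0.108), 2 (0.0758) or 3 (0.110). It also ended with sex as a covariate (0.0560) and without the 3 muscle-rich libraries (0.0968), and over 13 alternatives the adjusted p ran from 0.0259 to 0.119. The adipocyte median was 0.96 in saline while the camera direction was down (adjusted p = 0.884), and 2.38 in ATG, or 2.28 with Cidea at its bound (0.4). All 5 genes of squamous epithelium and cartilage did not pass in either, also adjusted over the list alone. Their medians were −0.64 and 0.12, the latter against a mean of −0.02 (camera adjusted p = 0.688 and 0.86). The 5 sex-linked genes did not pass either, 1 being higher in saline adjusted over the list alone. Their medians were −1.32, against a mean of 0.10, and 0.88 (camera adjusted p = 0.35 and 0.678).

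Among the largest changes outside the lists, Ntrk2 (chromosome 13, 58806472 to 59133970), the receptor of the neurotrophin BDNF, went from 51.7 ± 8.94 to 10.0 ± 1.69 CPM in saline and from 62.1 ± 11.98 to 11.7 ± 2.51 CPM in ATG. It fell by 2.37 (SE 0.19, edgeR QL adjusted p = 8.96e-06) and by 2.41 (SE 0.19, adjusted p = 4.18e-06) on the log2 scale. By edgeR QL, 1449 genes passed in saline, 740 higher and 709 lower, and 1838 in ATG, 853 higher and 985 lower. Of these, 128 were at least 2-fold higher and 246 at least 2-fold lower in saline, and 164 and 314 in ATG. The saline count was 889 without saline room air 2, 740 without saline room air 3, 955 without saline hyperoxia 1, 760 without saline hyperoxia 3 and 781 without the 3 muscle-rich libraries. The drug-injected count was 1152 and 1150 without ATG room air 1 and 3. Averaged over both injections, 1741 genes rose and 1785 fell. The saline and drug-injected comparisons, which share no library, had 506 higher and 529 lower genes in common, where independent lists of those sizes would have 40.0 and 44.3. Across the 15761 genes, which are not independent replicates, their log2 fold changes correlated with Pearson's r = 0.572 and Spearman's rho = 0.594.

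**Figure D2:**
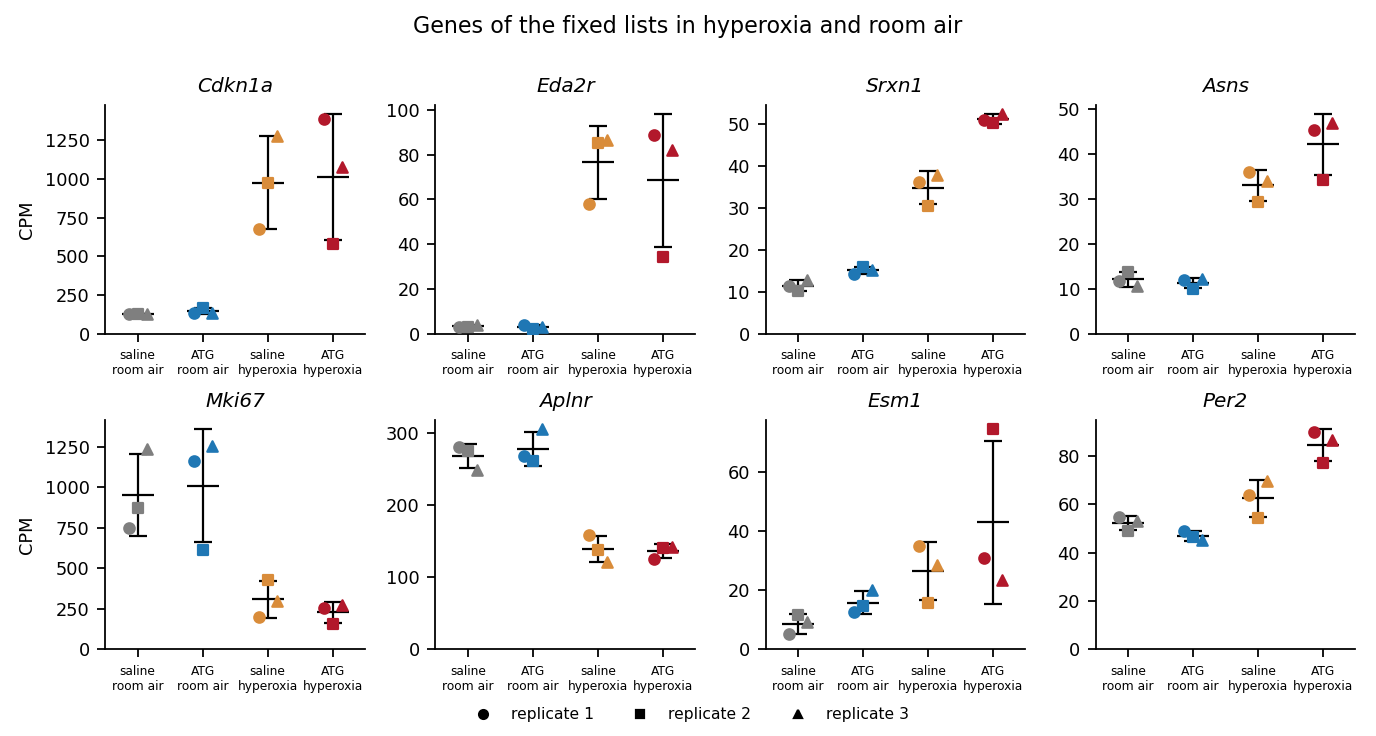
CPM of 8 genes in the 4 groups, each point 1 library (marker shape, replicate number) and each bar the mean ± SD of 3, with the vertical axes starting at 0. Cdkn1a, Eda2r, Srxn1 and Asns are higher and Mki67 and Aplnr lower in hyperoxia after both injections, as in Aplnr at 268 and 139 CPM in saline, while Esm1 spreads widely in hyperoxia and Per2 is highest in ATG hyperoxia at 84.3 CPM.

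Aurothioglucose was compared with saline in room air to ask what the drug changed without hyperoxia, the title of the series asking about pro-angiogenic pathways. NRF2 targets lay higher after the drug as a list, 22 of 26 with a positive fold change, and no gene passed on its own. The list had a median of 0.19 (camera adjusted p = 2.56e-08), and the call was lost (adjusted p = 0.0753 with an estimated correlation). Slc7a11 (chromosome 3, 50364936 to 50499087), the cystine transporter that feeds glutathione synthesis, averaged 22.2 ± 5.39 CPM after the drug and 13.1 ± 4.21 CPM after saline (n = 3), a log2 fold change of 0.76 (SE 0.22, edgeR QL adjusted p = 0.782). Txnrd1 averaged 61.8 ± 6.46 and 51.7 ± 2.40 CPM (0.26, adjusted p = 0.818), the drug above saline in 9 of 9 pairs of samples. The other antioxidant and metal-binding genes fixed beforehand had values of 0.40 (Srxn1), 0.35 (Gclm), 0.23 (Hmox1), −0.15 (Nqo1), 0.22 (Mt1) and 0.16 (Mt2), with adjusted p from 0.818 to 0.966. The vascular genes fixed beforehand had values of −0.05 (Vegfa), 0.06 (Kdr), 0.23 (Flt1), 0.09 (Pecam1), 0.07 (Angpt1) and 0.08 (Epas1), with adjusted p from 0.818 to 0.979.

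By edgeR QL 0 of 15761 genes passed in room air, 949 having an unadjusted p under 0.05 (486 higher, 463 lower). limma-voom also gave 0, DESeq2 gave 16 (7 higher, 9 lower), and without ATG room air 2 edgeR QL gave 1. The 5 genes with the smallest p, none passing (adjusted p = 0.265), were Rbm5 and Clk1, which act in splicing, at −0.55 and −0.70, Serac1 at −0.52, 1700017B05Rik at 0.53, and S1pr1, the sphingosine 1-phosphate receptor of endothelium, at 0.67. Each passed in DESeq2. Of the NRF2 targets 7 were higher adjusted over the list alone.

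The vascular lists were called higher in room air with all 6 samples. Of 34 angiogenic genes, 24 had a positive fold change, 34 did not pass over all genes and 1, S1pr1, did adjusted over the list alone. Their median was 0.09 (camera adjusted p = 0.00779, and adjusted p = 0.565 with an estimated correlation). It was 0.06 without saline room air 3 and 0.05 without ATG room air 3, which each ended the call, and 0.05 and 0.16 without ATG room air 1 and 2. Of 20 endothelial markers, 18 had a positive fold change and 20 did not pass, also adjusted over the list alone. Their median was 0.10 (camera adjusted p = 0.0134, and adjusted p = 0.565 with an estimated correlation). It was 0.04 without saline room air 3 and 0.05 without ATG room air 3, which each ended the call, as did sex as a covariate (0.04), and 0.04 without ATG room air 1. Saline room air held males only and ATG room air 2 females and 1 male.

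Among other lists in room air, 12 of 12 type 2 markers had a positive fold change and 4 passed adjusted over the list alone (median 0.23, camera adjusted p = 1.8e-08, and adjusted p = 0.287 with an estimated correlation). Type 1 markers had a median of 0.15 (camera adjusted p = 0.00136, and adjusted p = 0.434 with an estimated correlation), 0.22 with sex as a covariate, and 0.10 without saline room air 3, which ended the call. Integrated stress response genes had a median of 0.25 (camera adjusted p = 0.00203, and adjusted p = 0.434 with an estimated correlation), or 0.13 without ATG room air 3. For immediate early genes it was 0.27 (0.000193, and adjusted p = 0.434 with an estimated correlation), with 3 members higher adjusted over the list alone, 0.46 and 0.16 without ATG room air 1 and 2, and 0.56 with sex as a covariate. Erythroid genes had a median of 0.69 (camera adjusted p = 0.0301, and adjusted p = 0.574 with an estimated correlation). The call ended without saline room air 3 (0.66) or ATG room air 3 (0.38) and with sex as a covariate (0.60). Lower lists were interferon response genes at −0.25 (camera adjusted p = 0.0013, and adjusted p = 0.434 with an estimated correlation), ciliated markers at −0.27 (0.000219, and adjusted p = 0.434 with an estimated correlation) and club markers at −0.30 (0.0439, and adjusted p = 0.574 with an estimated correlation). The interferon median was −0.14 without saline room air 1, −0.15 without ATG room air 1 and −0.16 with sex as a covariate, with 1 member lower adjusted over the list alone. The ciliated call ended without ATG room air 3 (−0.14), and the club call without that library (−0.05), without saline room air 1 (−0.25) and with sex as a covariate (−0.26). The other lists did not pass camera. Among them median and mean differed in sign for cytokine genes (0.21 and −0.04), thymocyte genes (0.23 and −0.07) and squamous and cartilage genes (0.42 and −0.23).

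The same comparison was made in hyperoxia. Pde4b (chromosome 4, 102087332 to 102607275), a phosphodiesterase that degrades cyclic AMP, was higher after the drug, at 237 ± 34.7 against 81.7 ± 8.71 CPM (n = 3). Its log2 fold change was 1.54 (SE 0.21, edgeR QL adjusted p = 0.0457). The rule by which it was named requires that the groups not overlap. Slc7a11 averaged 49.7 ± 8.27 and 21.6 ± 1.08 CPM (1.20, adjusted p = 0.281), and Hmox1, the heme oxygenase, had a value of 0.78 (adjusted p = 0.134). These did not pass by edgeR QL and passed by DESeq2, by limma-voom and with no filter on low counts. Txnrd1 averaged 109 ± 2.72 and 87.9 ± 6.66 CPM (0.31, adjusted p = 0.623). Of 26 NRF2 targets 25 had a positive fold change, and 7 were higher adjusted over the list alone, with a median of 0.19 (camera adjusted p = 1.67e-15). This call held (adjusted p = 0.00852 with an estimated correlation).

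By edgeR QL 1 gene passed in hyperoxia, Pde4b, against 10 by DESeq2 (7 higher, 3 lower), 3 by limma-voom and 897 at an unadjusted p under 0.05. Pde4b no longer passed without saline hyperoxia 1 (1.49), 2 (1.504) or 3 (1.64), without ATG hyperoxia 1 (1.46) or 3 (1.50003), with sex as a covariate (1.52), without both Nppa-rich libraries (1.62) or without the 3 muscle-rich libraries (1.48), its adjusted p ranging up to 0.326 without 1 library. Without saline hyperoxia 1 the count was 2. In room air Pde4b averaged 277 ± 85.7 and 150 ± 38.5 CPM (0.89, adjusted p = 0.498), and the difference between the effects, 0.65, did not pass the interaction test (adjusted p = 1.00). The other genes fixed beforehand had values of 0.56 (Srxn1), 0.09 (Gclm), 0.12 (Nqo1), 0.19 (Mt1), 0.08 (Mt2), −0.03 (Vegfa), −0.00 (Kdr), 0.19 (Flt1), 0.03 (Pecam1), 0.06 (Angpt1) and 0.04 (Epas1), with adjusted p from 0.556 to 0.999.

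The angiogenic list was not called in hyperoxia (median 0.03, camera adjusted p = 0.119), 1 being higher adjusted over the list alone. It was called without saline hyperoxia 3 (0.07) or ATG hyperoxia 2 (0.04) and with the cardiac markers as a covariate (0.03). Endothelial markers were not called (0.04, camera adjusted p = 0.0941), 1 being higher adjusted over the list alone. Calls came without saline hyperoxia 1 (0.08) or 3 (0.06) or ATG hyperoxia 2 (0.07) and with sex (0.05) or cardiac markers (0.05) as covariates. The median was −0.02 without saline hyperoxia 2. Integrated stress response genes lay higher (0.33, camera adjusted p = 3.53e-06, and adjusted p = 0.128 with an estimated correlation), 2 adjusted over the list alone, with a median of 0.17 without saline hyperoxia 1. Clock genes lay higher (0.18, camera adjusted p = 0.000563, and adjusted p = 0.054 with an estimated correlation), 4 adjusted over the list alone.

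Lists that moved with the cardiac, muscle and thymocyte transcripts of a few libraries stood beside these. Cell cycle genes lay lower (−0.34, camera adjusted p = 2.04e-06, and adjusted p = 0.582 with an estimated correlation). Their median was −0.10 without saline hyperoxia 2 and −0.12 without ATG hyperoxia 2, which each ended the call, and turned to 0.11 without both, the libraries with Nppa at 270 and 1108 CPM. It was −0.53 without saline hyperoxia 1, −0.52 without ATG hyperoxia 3 and −0.20 with sex as a covariate. Thymocyte genes lay lower (−3.02, camera adjusted p = 5.76e-10, and adjusted p = 0.128 with an estimated correlation), 6 of 6 adjusted over the list alone, or −1.90 without saline hyperoxia 2, where Rag1 stood at 39.2 CPM, and −1.97 without both Nppa-rich libraries. B, T and NK cell markers lay lower (−0.61, camera adjusted p = 3.53e-06, and adjusted p = 0.128 with an estimated correlation), or −0.38 without both Nppa-rich libraries. Skeletal muscle genes lay lower (−1.57, camera adjusted p = 0.00237, and adjusted p = 0.509 with an estimated correlation), 3 adjusted over the list alone. Their median turned to 0.07 without saline hyperoxia 1, where Myh8 stood at 175 CPM, and was −1.73 without ATG hyperoxia 3, which ended the call. It was −2.48 and −2.52 without saline hyperoxia 2 and 3, −3.31 without ATG hyperoxia 2 and −3.45 without both Nppa-rich libraries.

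Neutrophil markers lay higher in hyperoxia after the drug (0.63, camera adjusted p = 1.92e-06, and adjusted p = 0.292 with an estimated correlation), 1 adjusted over the list alone, with medians of 1.12, 0.33 and 0.41 without saline hyperoxia 1, 2 and 3 and 0.31 without both Nppa-rich libraries. Cytokine genes lay higher (0.25, camera adjusted p = 0.00646, and adjusted p = 0.509 with an estimated correlation). That call ended without saline hyperoxia 2 (0.10), ATG hyperoxia 3 (0.17) or both Nppa-rich libraries (0.11), and the median was 0.38 without ATG hyperoxia 1. Glucocorticoid-responsive genes lay higher (0.33, camera adjusted p = 0.000247, and adjusted p = 0.128 with an estimated correlation), 1 adjusted over the list alone, or 0.18 without ATG hyperoxia 2 and 0.14 with the cardiac markers as a covariate. Without both Nppa-rich libraries it was 0.10 and the call ended. The other lists did not pass camera. Among them median and mean differed in sign for metallothionein and heat shock genes (−0.02 and 0.01), macrophage markers (0.01 and −0.03) and squamous and cartilage genes (0.13 and −0.19).

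Averaged over room air and hyperoxia, aurothioglucose was compared with saline in all 12 samples. Slc7a11 rose by 0.98 (SE 0.15, edgeR QL adjusted p = 0.0478). S1pr1 (chromosome 3, 115710433 to 115715055) rose from 178 ± 8.96 to 283 ± 46.2 CPM in room air and from 210 ± 25.2 to 314 ± 46.5 CPM in hyperoxia, an average of 0.63 (SE 0.09, adjusted p = 0.0401). Bcl6b (chromosome 11, 70224127 to 70229798), a transcriptional repressor expressed in endothelium, rose by 0.54 (SE 0.09, adjusted p = 0.0478), and Dusp8 (chromosome 7, 142079487 to 142095907), a phosphatase of MAP kinases, by 0.83 (SE 0.13, adjusted p = 0.0478). Clk1 (chromosome 1, 58411988 to 58424088), a kinase of splicing factors, fell by 0.54 (SE 0.09, adjusted p = 0.0478), from 127 ± 12.7 to 78.0 ± 11.6 CPM in room air and from 106 ± 3.86 to 81.6 ± 11.4 CPM in hyperoxia. The rule by which these genes were named requires that the groups not overlap in either oxygen condition. Pde4b (1.21, adjusted p = 0.0111) and 1700017B05Rik (0.47) passed too and are named after their values were seen.

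In all, 7 genes passed in the average by edgeR QL, 6 higher and 1 lower, against 96 by DESeq2 (62 higher, 34 lower), 9 by limma-voom and 1335 at an unadjusted p under 0.05. The share of higher calls was 85.7%, against 64.6% by DESeq2, 66.7% by limma-voom and 3 of 3 genes with RLE size factors. The count was 0 without saline room air 1, saline room air 2 or saline hyperoxia 2, and 24 without ATG room air 1. It was 1 without saline room air 3, ATG room air 3 or ATG hyperoxia 1, 2 without ATG room air 2 or ATG hyperoxia 3, and 3 without saline hyperoxia 3. It was 4 with sex as a covariate, 2 without the Nppa-rich libraries and 21 with the cardiac markers as a covariate. Over all alternatives the value of S1pr1 lay between 0.56 and 0.68 and it passed in 11 of 21, that of Slc7a11 between 0.87 and 1.09, passing in 6, and that of Clk1 between −0.58 and −0.46, passing in 6. Dusp8 lay between 0.72 and 0.92, passing in 6, and Bcl6b between 0.45 and 0.60, passing in 7. S1pr1 no longer passed without saline room air 1 (0.65), 2 (0.61) or 3 (0.63), ATG room air 2 (0.64) or 3 (0.56), saline hyperoxia 1 (0.60) or 2 (0.60), or ATG hyperoxia 1 (0.56) or 3 (0.65). Slc7a11, Dusp8, Clk1 and Bcl6b did not pass without any 1 of the same libraries, with RLE size factors, with sex as a covariate, without both Nppa-rich libraries or without the 3 muscle-rich ones, and S1pr1 did not pass without the last (0.56). Without saline hyperoxia 3, Slc7a11 (0.99), Dusp8 (0.89) and Clk1 (−0.55) did not pass, and without ATG hyperoxia 2 Dusp8 (0.84) did not.

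The NRF2 list was higher in the average, with 24 of 26 fold changes positive and a median of 0.19 (camera adjusted p = 5.13e-18). The call held (adjusted p = 0.00564 with an estimated correlation). Of its members 1, Slc7a11, passed over all genes and 14 were higher adjusted over the list alone, among them Srxn1 (0.48), Hmox1 (0.51), Txnrd1 (0.28) and Gsr (0.24), the glutathione reductase. Fth1 (0.38) and Ftl1 (0.36), the ferritin chains, were also among them and are uncertain because many near-identical copies share their reads. Of 34 angiogenic genes, S1pr1 passed over all genes and adjusted over the list alone, and the median was 0.06 (camera adjusted p = 0.00494, and adjusted p = 0.381 with an estimated correlation). It was 0.04 without saline hyperoxia 2, which ended the call, 0.04 without ATG room air 3 or hyperoxia 1, and 0.10 without ATG hyperoxia 2. Of 20 endothelial markers, 20 did not pass over all genes and 2, Tmem100 (0.40) and the junction gene Cldn5 (0.37), were higher adjusted over the list alone. Their median was 0.07 (camera adjusted p = 0.00523, and adjusted p = 0.381 with an estimated correlation), or 0.03 without saline hyperoxia 2, which ended the call. Markers of cell types moved beside these. Type 2 (0.15, camera adjusted p = 1.63e-05), type 1 (0.11, 0.00998), neutrophil (0.47, 6.66e-05) and erythroid genes (0.69, 0.0215) lay higher. Thymocyte (−1.53, 1.63e-05), B, T and NK (−0.35, 0.00178) and ciliated markers (−0.16, 0.00352) lay lower. These 7 calls were lost with an estimated correlation (adjusted p from 0.275 to 0.506 with an estimated correlation). The type 1 call ended without saline room air 3 (0.076), saline hyperoxia 2 (0.074) or both Nppa-rich libraries (0.016), and the median was 0.065 without ATG hyperoxia 2. The erythroid call ended without saline room air 3 (0.67), ATG room air 3 (0.71), saline hyperoxia 1 (0.63) or 3 (0.71) or ATG hyperoxia 1 (−0.05), and the median was 1.22 without both Nppa-rich libraries. The B, T and NK call ended without both Nppa-rich libraries (−0.17), and the ciliated call without ATG room air 3 (−0.07). Without saline hyperoxia 2 the thymocyte median was −0.95 and the ciliated one −0.09, and without saline hyperoxia 1 the neutrophil median was 0.78. Integrated stress response (0.17, camera adjusted p = 1.57e-06), immediate early (0.20, 0.000181), glucocorticoid-responsive (0.18, 0.00166), clock (0.12, 0.00814), HIF (0.12, 0.0296) and cytokine genes (0.16, 0.0369) lay higher and cell cycle genes lower (−0.18, 0.00814). These calls too were lost (adjusted p from 0.143 to 0.691 with an estimated correlation). Adjusted over the list alone, 3 integrated stress response, 3 immediate early, 3 glucocorticoid-responsive, 1 clock, 1 type 2 and 1 neutrophil gene were higher and 3 thymocyte genes lower. The cell cycle call ended without saline room air 3 (−0.095), ATG room air 2 (−0.063), saline hyperoxia 2 (−0.051) or ATG hyperoxia 2 (−0.051), and the median was 0.066 without both, −0.28 without saline hyperoxia 1 and −0.29 with sex as a covariate. The HIF call ended without saline room air 3 (0.098), ATG room air 2 (0.15) or 3 (0.071), saline hyperoxia 2 (0.12), ATG hyperoxia 2 (0.12) or both of these (0.12), and the median was 0.074 without ATG hyperoxia 3. The cytokine call ended without saline room air 3 (0.17), ATG room air 2 (0.20), saline hyperoxia 2 (0.12), ATG hyperoxia 3 (0.11) or both Nppa-rich libraries (0.18), and the median was 0.29 and 0.27 without saline room air 1 and saline hyperoxia 3. The immediate early median was 0.048 without both Nppa-rich libraries and 0.11 without saline hyperoxia 1, the stress response one 0.25 without saline hyperoxia 3 and the glucocorticoid one 0.27 without ATG hyperoxia 3. Of the 30 lists, 17 were called with the preset correlation, 13 higher and 4 lower, and 1, the NRF2 list, with an estimated one. Median and mean differed in sign for club markers (0.02 and −0.05), macrophage markers (−0.03 and 0.01), adipocyte genes (0.19 and −0.07) and sex-linked genes (−0.43 and 0.11).

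**Figure D3:**
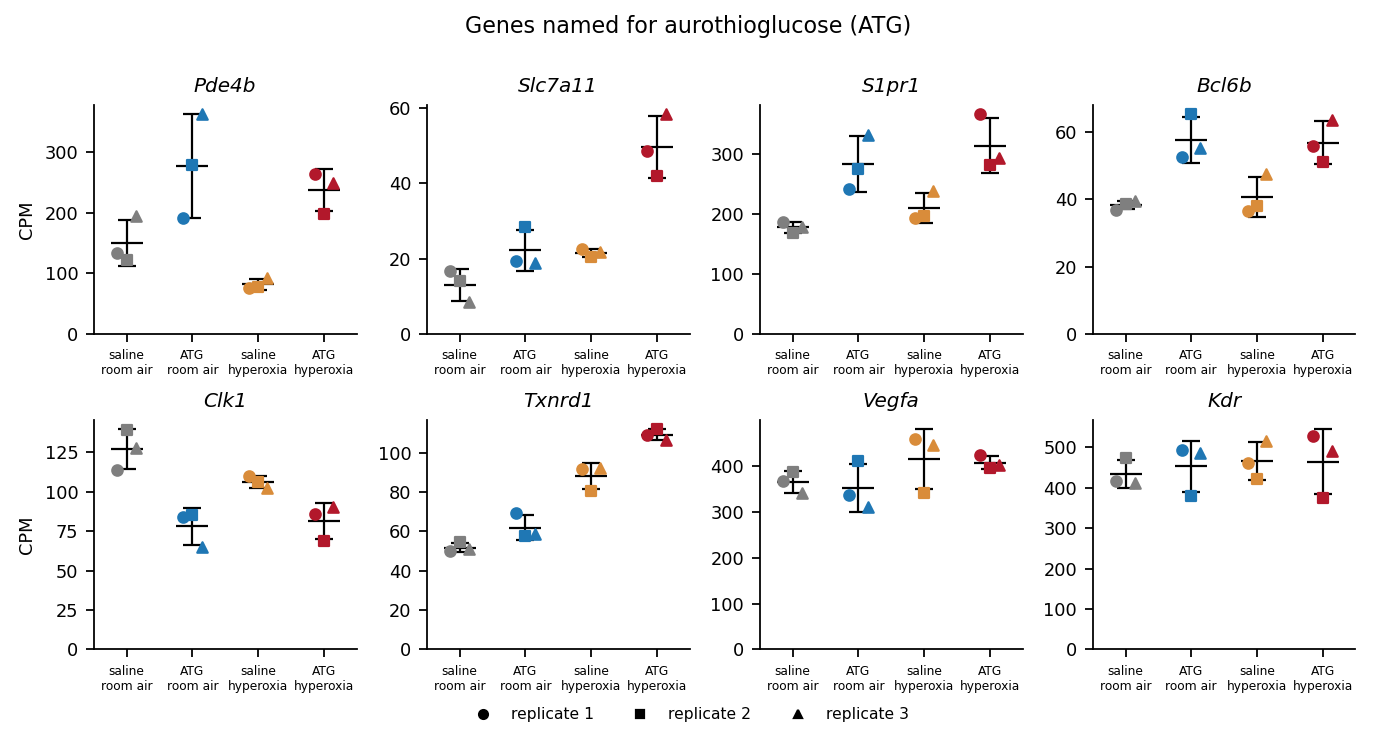
CPM of 8 genes named for the drug (ATG) in the 4 groups, each point 1 library (marker shape, replicate number) and each bar the mean ± SD of 3, with the vertical axes starting at 0. Slc7a11, S1pr1 and Bcl6b are higher and Clk1 lower after the drug under both oxygen conditions, with S1pr1 at 178 and 283 CPM in room air, while Pde4b overlaps in room air and is higher in hyperoxia, and Vegfa and Kdr overlap.

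Whether the drug acted differently in hyperoxia was tested as an interaction. The 5 genes with the smallest p, none passing (adjusted p = 1.00), were Flad1 (1.38), Serac1 (0.60), Per2 (0.59), Rag1 (−4.38) and Rprd1b (−0.46). By edgeR QL 0 genes passed, as by DESeq2 (0) and limma-voom (0), and 465 had an unadjusted p under 0.05. Camera called 14 of the 30 lists with the preset correlation and 0 with an estimated one (adjusted p from 0.424 to 0.692 with an estimated correlation). Across the 15761 genes, which are not independent replicates, the drug effects in room air and in hyperoxia correlated with Pearson's r = 0.0420 and Spearman's rho = 0.171, and with r = 0.207 among genes of at least 5 CPM. Pearson's r was −0.0583 with sex as a covariate and, with genes filtered anew, 0.00297 without both Nppa-rich libraries and −0.0130 to 0.0530 without 1. No library was shared, and 58.2% of genes had the same sign.

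**Figure D4:**
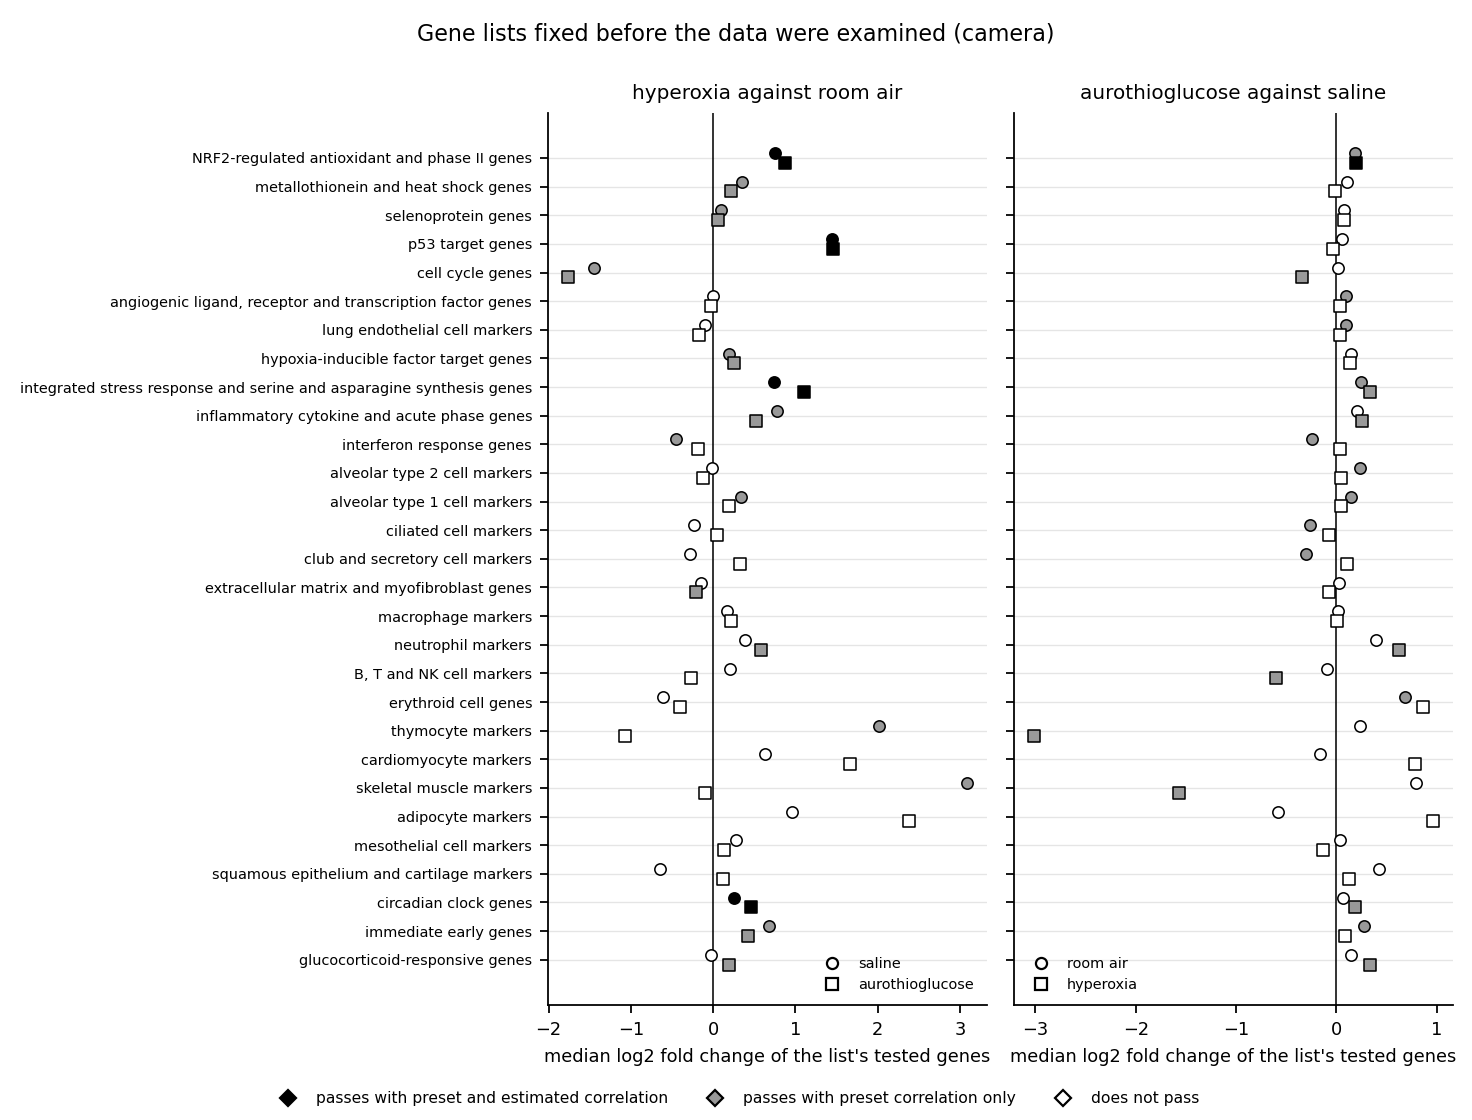
Median log2 fold change of 29 of the 30 gene lists fixed beforehand (the sex-linked list is not drawn), for hyperoxia against room air (left; circles saline, squares aurothioglucose) and aurothioglucose against saline (right; circles room air, squares hyperoxia). Black symbols passed camera with the preset and an estimated correlation, grey ones with the preset correlation only, white ones did not pass, and the NRF2 list stands at 0.75 and 0.87 on the left and at 0.19 and 0.19 on the right.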

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

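The tests of heart tissue and of a response to oxygen were chosen after the cardiac markers had been seen, as were the settings that leave out those libraries, use their markers or put sex as a covariate into the list tests.

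Camera with the preset correlation called 14 lists in the interaction of drug and oxygen. By edgeR QL 0 single genes passed it (465 at an unadjusted p under 0.05), as by DESeq2 (0) and limma-voom (0). The median differences of the drug's log2 fold change, hyperoxia minus room air, were −2.48 for thymocyte genes (adjusted p = 2.01e-06), −2.11 for skeletal muscle (0.000264), −0.62 for B, T and NK cells (0.00177), −0.36 for the cell cycle (4.28e-05), −0.18 for type 2 cells (0.00064) and −0.14 for type 1 cells (0.0495). They were 2.34 for sex-linked genes (0.0287), 1.54 for adipocyte genes (0.0495), 1.06 for cardiomyocyte genes (0.0275), 0.44 for club cells (0.00489), 0.24 for interferon response genes (0.0018), 0.24 for neutrophils (0.0181), 0.21 for ciliated cells (0.0287) and 0.067 for clock genes (0.0495). With an estimated correlation 0 of the 14 passed (adjusted p from 0.424 to 0.692).

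Most of these calls ended without 1 library. The thymocyte median kept its call at −1.16 without saline hyperoxia 2, −3.82 without saline room air 3, −1.05 without both Nppa-rich libraries and −1.43 with sex as a covariate. The skeletal muscle call ended without saline hyperoxia 1 (−0.66), and the median was −4.63 without ATG hyperoxia 2 and −4.88 without both Nppa-rich libraries. The cell cycle call ended without saline hyperoxia 2 (−0.12) or ATG hyperoxia 2 (−0.17), and the median was −0.20 without ATG room air 3 and turned to 0.01 without both Nppa-rich libraries and with sex as a covariate. The B, T and NK call ended without ATG room air 2 (−0.33), ATG hyperoxia 2 (−0.40) or both Nppa-rich libraries (−0.27), and the median was −0.33 without saline room air 1. The interferon median was 0.39 without saline hyperoxia 2. Without ATG hyperoxia 2 the cardiomyocyte list was called in the opposite direction (−0.97, camera adjusted p = 0.0108) and the adipocyte median was −2.19, not called. With the cardiac markers as a covariate they were −0.05 and −0.03. The ciliated call ended without saline room air 3 (0.21), ATG room air 3 (0.06), saline hyperoxia 3 (0.06) or ATG hyperoxia 2 (0.07), without both Nppa-rich libraries (0.13) and with sex (0.13) or the cardiac markers (0.11) as a covariate. The club call ended without saline room air 1 (0.39), ATG room air 3 (0.24), saline hyperoxia 3 (0.32) or ATG hyperoxia 2 (0.26) and with sex as a covariate (0.37). The neutrophil call ended without saline room air 2 (0.10), ATG room air 1 (0.03) or 3 (0.24), or saline hyperoxia 2 (−0.08) or 3 (0.06), without both Nppa-rich libraries (−0.03) and with sex as a covariate (0.24). Its median was 0.47 without saline room air 3, 0.58 without ATG room air 2, 1.02 without saline hyperoxia 1, 0.079 without ATG hyperoxia 3 and 0.49 with the cardiac markers as a covariate. The cardiomyocyte call ended without saline room air 3 (0.93), ATG room air 2 (0.94) or 3 (0.95), or saline hyperoxia 1 (0.74) or 3 (0.67), without both Nppa-rich libraries (0.19) and with sex as a covariate (0.99), and the median was 2.38 without saline hyperoxia 2. The adipocyte call also ended without saline room air 2 (1.46) or 3 (2.12), ATG room air 2 (1.72) or 3 (1.63), or saline hyperoxia 1 (1.74) or 3 (1.30), with RLE size factors (1.54) and with sex as a covariate (1.59). The median was 3.12 without ATG room air 1, 2.50 without saline hyperoxia 2, and 2.31 and 2.42 without ATG hyperoxia 1 and 3. The type 1 call ended without saline room air 1 (−0.13) or 3 (−0.07), ATG room air 1 (−0.10) or 2 (−0.09), saline hyperoxia 1 (−0.12) or 3 (−0.06), or ATG hyperoxia 1 (−0.12) or 3 (−0.17), with RLE size factors (−0.14) and with the cardiac markers as a covariate (−0.14). The median was −0.22 without saline hyperoxia 2 and −0.23 without both Nppa-rich libraries. The sex-linked call ended without saline room air 3 (2.26), ATG room air 1 (1.76) or 3 (1.75), saline hyperoxia 1 (1.74) or 2 (1.75), ATG hyperoxia 1 (1.77) or 2 (2.03), or both Nppa-rich libraries (1.46). The median was 6.93 without ATG room air 2, 7.53 without saline hyperoxia 3 and −0.21 with sex as a covariate. The clock call ended without saline room air 1 (0.04), 2 (0.08) or 3 (0.01), ATG room air 2 (−0.00) or 3 (0.14), saline hyperoxia 2 (0.12) or 3 (0.06), or ATG hyperoxia 1 (0.10) or 2 (0.05), without both Nppa-rich libraries (0.066) and with sex (0.10) or the cardiac markers (0.028) as a covariate. The median was 0.11 without ATG room air 1, 0.015 without saline hyperoxia 1 and 0.15 without ATG hyperoxia 3.

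Cardiac transcripts stood high in saline hyperoxia 2 and ATG hyperoxia 2, with Nppa at 270 and 1108 CPM and Myh6 at 919 and 1645 CPM. Had hyperoxia raised them in all its libraries, the other 4 would lie above the 6 room air ones. Their mean log2 CPM of the cardiomyocyte list lay lower (−0.45, 4.54 ± 0.23 against 4.99 ± 0.28, SD). This argues against a shared response, not against one in some samples. Of 22 cardiomyocyte genes outside the list, 20 (90.9%) were higher in both libraries than in each of the other 10, 18 of 20 when the genes seen beforehand are left aside, and of the list 9 of 10 were. Heart tissue in those lung samples is therefore a candidate explanation, in whole lungs with no sort that would remove it, although each of the 22 genes was also counted in each of the other 10 libraries and Myh6 stood there at 89.3 to 244 CPM. Both libraries fall in hyperoxia groups, and no other biological explanation was tested.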

How the results depend on the processing

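Leaving out both Nppa-rich libraries, these and the Myh8-rich one, the cardiac-marker covariate and sex as a covariate for lists were chosen after seeing the data. Within 1.5 times of the reported value were 89 of 127 counts of genes, 28 being lower and 10 higher. Of 1415 list values under alternatives 1157 kept direction and call, 232 lost the call, 8 gained it, 4 changed sign without a call and 14 reversed, and of 5244 gene values 4780 kept both, 417 lost the call and 2 reversed. Genes for the drug in room air were 16 by DESeq2 and 0 to 1 without 1 library. In hyperoxia they were 10 by DESeq2, 3 by limma-voom, 3 with no filter, 0 with sex as a covariate, 0 without the 2 Nppa-rich libraries, 0 without 3 libraries and 0 to 2 without 1 library. For the averaged drug they were 96 by DESeq2, 3 with RLE size factors, 24 with no filter, 4 with sex (3 shared with the reported 7), 2 without the 2 libraries, 0 without 3, 21 with the cardiac covariate and 0 to 24 without 1 library. For hyperoxia they were 781 without 3 libraries and 740 to 1168 without 1 library in saline, and 1150 to 2045 without 1 library in aurothioglucose. The replicate numbers name no litter or day and did not pair the samples: 4 of 18 correlations of same-numbered deviations passed 0.1 (range −0.261 to 0.288). With the replicate number as a block the averaged drug count was 3 and the other counts stayed within 1.5 times. Skeletal muscle in saline (2.42) and type 1 (−0.14), adipocyte (1.27) and clock genes (0.071) in the interaction then lost their calls. With an estimated correlation the NRF2 list in room air (0.19) and the angiogenic list in room air (0.0911) and in the average (0.0632) lost their calls, the estimated correlations being 0.0569, 0.155 and 0.153 against the preset 0.01. Without 1 library the angiogenic median ran from 0.0511 to 0.164 in room air, from 0.00417 to 0.0704 in hyperoxia and from 0.0403 to 0.10 in the average, and in hyperoxia it was called with the cardiac covariate (0.0253). Reversals were cell cycle genes for the drug in hyperoxia (0.11), in the average (0.0658) and in the interaction (0.012) without the 2 libraries, and in the interaction with sex (0.00607). Others were cardiomyocyte (−0.0538) and adipocyte genes (−0.0301) in the interaction with the cardiac covariate, neutrophil genes there without the 2 libraries (−0.0281), sex-linked genes with sex (−0.21), Myh3 in saline hyperoxia (−0.67) and Myl1 in averaged hyperoxia (−1.34) without 3 libraries. Without 1 library, reversing medians ran from −3.31 to 0.0694 for skeletal muscle genes under the drug in hyperoxia, from −0.972 to 2.38 for cardiomyocyte and −2.19 to 3.12 for adipocyte, −0.0800 to 1.02 for neutrophil and −0.00144 to 0.15 for clock genes in the interaction, and from −0.0503 to 0.965 for erythroid genes under the averaged drug. The drug effects in room air and hyperoxia correlated at 0.207 for genes of at least 5 CPM, −0.0583 with sex, 0.00297 without the 2 libraries and −0.0130 to 0.0530 without 1. Hyperoxia effects correlated at 0.807, 0.487, 0.452 and 0.408 to 0.510, against 0.572. The cause was not tested. Fits without a library have fewer samples and filter genes anew, so gene sets can differ. Without 3, the lone saline hyperoxia sample is assumed to vary like other groups. Against TMM, RLE size factors moved the median log2 fold change of all genes by at most 0.0069 over the contrasts. Depth limits low genes: in the smallest library, of 14331749 counts, a floor of 3 counts is 0.205 CPM.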

Other observations

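The tests of sex, of heart tissue and of the drug on the NRF2 list, of splicing genes and of endothelial RNA were chosen after the results they bear on had been seen, as was the exact permutation of list means.

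Beyond the lists, some of the largest rises in hyperoxia were in genes that stood near the floor in room air. Ano3, a membrane protein of the anoctamin family, went from 0.555 ± 0.0712 to 21.4 ± 7.98 CPM in saline and from 0.211 ± 0.199 to 21.4 ± 14.4 CPM in ATG (n = 3), passing by edgeR QL (adjusted p = 0.000363 and 0.000133) and not by limma-voom. Gdf15, a secreted stress protein and p53 target, rose by 3.30 and 2.85 in every setting run. Pde4b was lower in hyperoxia than in room air in saline (−0.88, edgeR QL adjusted p = 0.0159) and did not pass in ATG (−0.23, adjusted p = 0.53), and the difference did not pass the interaction test (0.65, adjusted p = 1.00).

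For the averaged drug contrast, Creg1 (0.33), Kcne2 (0.67), Srxn1 (0.48), Hmox1 (0.51) and Rbm5 (−0.39) missed the threshold with edgeR QL adjusted p = 0.0592. Permuting the drug labels within the oxygen conditions (400 arrangements, exact, two-sided) gave p = 0.005, the smallest they can give, for the mean of the NRF2 list and of the clock list. The same test gave 0.01 for the integrated stress response (camera lost this call and the clock one, adjusted p = 0.143 with an estimated correlation), 0.035 for type 2 markers, 0.07 for angiogenic genes and 0.08 for endothelial markers. Adjusted over the 30 lists, 0 passed (NRF2 and clock 0.075, integrated stress response 0.1), and a lone list cannot go below 0.15. For hyperoxia, permuted within the injections, 12 of 30 lists passed, with an adjusted p of 0.0136 for NRF2 and p53 targets and the cell cycle and 0.0375 for cytokine genes.

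Xist was counted in libraries with Y-linked counts (250 to 377 counts, 1.23% of the female level), and the 4 Y-linked genes were counted in libraries with high Xist at 0.906% to 1.10% of the male level. Reads of the X-linked partners counted on the Y-linked genes would give each gene its own share, but the largest share was 1.21 times the smallest, which argues against it. Reads passing between the 12 libraries would leave no abundant gene close to absent in any library. Of 7835 genes with a mean of at least 20 CPM, 0 had a library below 0.771% of the pooled level, 0.5 times the smallest share that Xist and the Y-linked genes reached. Those shares were 1.54% to 2.89%, and Nppa was at most at 2.36% of its pool in its lowest library. Exchange of reads between libraries stays a candidate explanation that this scan does not exclude, and no biological one was tested.

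The NRF2 list was higher after aurothioglucose. With sex as a covariate the averaged median was 0.195, and without the 2 libraries rich in cardiac transcripts it was 0.172, and the list kept its call in both, which argues against sex and against heart tissue as the whole cause. What stays open is whether the drug raised it, since the exact test gave an adjusted p of 0.075 over the lists while 0.005 alone was the smallest p the arrangements allow. The drug is thus a hypothesis that these samples cannot settle.

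Further hypotheses were tested once each. That aurothioglucose moves genes the way hyperoxia does was not borne out: the effects correlated across genes with r = 0.130, and permuting the drug labels gave an exact p of 0.225. That splicing genes fall with Clk1 could not be decided: 17 of 23 were lower, with a median of −0.14 and an exact p of 0.05, or 0.155 without the genes already seen. A larger share of endothelial RNA would raise its markers by about the 0.63 (SE 0.09) by which S1pr1 rose. The median of the 20 markers was 0.068 (SD over the markers 0.12), the highest being Tmem100 at 0.40, which argues against such a share as the whole cause.

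Other splits of the samples were fitted for each count. For 3 against 3 samples the 10 splits are too few for a share under 0.05. The real and the highest other count were 0 and 3 for the drug in room air, where each of the 10 splits gives as many as 0 by construction. They were 1449 and 0 for hyperoxia in saline (1 split) and 1838 and 5 for hyperoxia in ATG (1 split). For the drug in hyperoxia they were 1 and 83, with 3 splits giving as many. The split with 83 put saline hyperoxia 1 and 2 with ATG hyperoxia 2, the libraries richest in Myh8 and Nppa, which points to a structure of the samples other than the drug. Within strata, 4 of 100 drawn splits gave as many as the 7 genes of the averaged drug (highest other 15) and 1 of 100 as many as the 3526 of averaged hyperoxia (highest other 3), where 200 are possible. The exact hypergeometric 95% bounds of the share over all of them reach 3.00% for hyperoxia, which is under 0.05. They reach 7.50% for the drug, so the draws do not settle whether its share lies under 0.05. Such shares take the samples as independent, which the labels do not tell. For the interaction the real count was 0, so each of the 100 splits gives as many by construction (highest other 15), and the count bears on no call.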
